A study of Homo sapiens with 6 samples.

How the data were processed

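RNA was measured by sequencing in 6 libraries from 2 established human tumour cell lines: CHLA-266, a line from an atypical teratoid/rhabdoid tumour, and Daoy, a line from a medulloblastoma of the Sonic hedgehog (SHH) type. In each line, per the labels, 1 library came from cells with a scrambled control short hairpin RNA (shRNA) and 2 from cells with an shRNA against HHIP-AS1, a long non-coding RNA. Libraries were made from total RNA with a TruSeq RNA version 2 kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. That kit does not mark strand.

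The authors deposited 1 table of CPM (reads scaled to a common library total) for 58830 genes, all by gene symbol or clone name. The submitters' processing notes name STAR 2.4.1d, Bowtie2 2.2.5, Partek and the human build hg38. The role and order of these tools, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The CPM of a column sums to 568908 to 661705 over the listed genes, so the total used for scaling exceeded the listed reads. Low values lay at whole multiples of 1 step per library, the CPM of 1 read, and this step gave implied totals of 48.5 to 61.9 M (M, 1000000 reads). Between 82.8% and 83.5% of values of under 1000 reads were whole within a tolerance of 0.05 reads. Whole reads were therefore not recovered for all genes, and no count model was used. All 37 mitochondrial genes are listed at 0 in all 6 libraries, so a 0 in this table can be a choice of processing.

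The table heads 2 of its columns with the same name, that of the first HHIP-AS1 shRNA in CHLA-266. Both belong to the CHLA-266 knockdown group, but which shRNA each holds was not settled, and they are called CHLA-266 knockdown a and b, letters that pair with nothing. The tests planned for each shRNA across the lines, and the fits with the shRNA number as a term, were therefore run both ways, with a or with b taken as shRNA 1, and only as alternatives, since neither way is known to be right. Gene levels and changes by shRNA number are given for Daoy only, with 1 library each, and apart from the Poisson test of HHIP-AS1 reads no test was made on them. The labels do not say whether the libraries of a line came from separate cultures. Per the sample titles, the knockdown libraries of a line hold different shRNAs, so no condition was repeated. The p-values therefore measure the spread between these libraries, which may be technical. That spread also holds differences between shRNAs and, in the fit over both lines, between the lines' responses. A lack of calls can come from such differences. No library repeated another: at most 2.61% of values with a mean of at least 1 CPM were identical between any pair of libraries.

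Tests used limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend on the mean, 2-sided) on log2(CPM + 1), for the 15214 genes with a mean of at least 1 CPM over the 6 libraries. P-values were adjusted over these genes by the Benjamini-Hochberg method, with a threshold of 0.05. A change is a difference on the log2(CPM + 1) scale, which understates changes of genes at low levels. Knockdown was compared with control over both lines with the line as a term (3 residual degrees of freedom), and within each line, and between the lines' responses, in a fit with 1 mean per line and treatment (2 residual degrees of freedom). Each line has 1 control, whose spread cannot be measured and is assumed to equal that of the shRNA libraries. Daoy was compared with CHLA-266 in the fit with line and treatment. Changes in the 4 knockdown-control pairs were also counted without a model, at a limit of 1.5-fold in 1 direction in all 4 pairs. Because the shRNA libraries of a line share its control, agreement between them was set beside 100 simulations of unchanged libraries.

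On simulated data for 15214 genes, 200 were changed and each gene had 1 spread, taken from the fit with line and treatment. The comparison over both lines recovered 65 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 10 false calls. The same test recovered 9 and 93 of 100 within CHLA-266 with 16 false calls, 11 and 95 within Daoy with 14 false calls, and 1 and 46 for the difference between lines with 4 false calls. These shares hold for 200 changed genes and for noise that is independent between genes and equal in both lines. The measured changes varied more in Daoy (SD 0.38 and 0.61) than in CHLA-266 (SD 0.29 and 0.26). Recovery within a line may therefore differ from these shares. With few changed genes the adjustment is stricter, so a lack of calls does not exclude a few genes changed 2-fold. A list of 30 genes shifted by 0.5 on the log2 scale was found, with 0 other lists called. The simulated genes varied independently of each other, unlike measured genes of a list. This check therefore cannot show how often a list of correlated genes is called falsely.

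Gene lists were fixed before the data were examined: 21 lists with 400 entries, all matched, 5 of them through an older symbol. Of these, 18 had at least 5 tested genes: Hedgehog pathway components, Hedgehog target genes, cytoplasmic dynein 1 subunits, dynactin and dynein regulators, mitosis, DNA replication, p53 targets, apoptosis regulators, interferon response, NF-kB and cytokines, unfolded protein and integrated stress response, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, extracellular matrix and mesenchymal genes, neuronal differentiation, and neural stem and progenitor genes. The remaining lists, markers of blood and immune, epithelial and endothelial cells, had 1, 4 and 1 tested genes and are given as values. Lists were tested with limma's camera (inter-gene correlation preset at 0.01, and again estimated), adjusted over the 18 lists. With an estimated correlation, camera tests on the 2 or 3 residual degrees of freedom, so hardly any list can pass, whatever its correlation. A call lost there does not show that correlated genes made it. Calls with the preset correlation may in turn be too many where the genes of a list move together.

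Most genes named in the text were set by a rule, also fixed before the data were examined, and a few others, such as DYNC1I2P1, were added. The part of the rule on shRNAs was planned across the lines. It was applied to Daoy alone because the shRNA of the CHLA-266 columns was not settled. The rule takes HHIP-AS1, HHIP, DYNC1I2, GLI1, PTCH1 and SMARCB1, and the 12 higher and 12 lower genes with the largest smallest change over the 4 pairs. It adds the 5 genes in each direction with the largest change and a mean of at least 10 CPM for each line, for the difference between lines and for the Daoy shRNAs, and the 8 in each direction for Daoy against CHLA-266. From each list it takes up to 4 members with a mean of at least 5 CPM. Some genes the rule takes are not reported here. Locations, gene types, GC content and 3′ untranslated regions were taken from GENCODE version 29 (GRCh38), in which 13708 of the tested genes (90.1%) were found by symbol. Reads of HHIP-AS1 were compared between libraries with an exact Poisson ratio test, with 95% intervals that cover counting error only, since reads without molecular identifiers are not independent molecules.

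Other pseudocounts, filters, scalings and eBayes without a trend were tried, each library was left out in turn, and, after the data were seen, a smooth trend on GC content and transcript length was removed, genes were limited to protein-coding ones, and the listed genes were scaled to a common sum. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.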

Results

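The data were CPM values of 6 RNA-seq libraries, 3 from the rhabdoid tumour line CHLA-266 and 3 from the SHH medulloblastoma line Daoy. In each line 1 library carried a scrambled shRNA and 2 carried an shRNA against HHIP-AS1, and the title of the series ties this RNA to SHH signalling. Implied read totals, in units of 1000000 reads (M), were 61.9 M in the CHLA-266 control, 57.0 and 48.5 M in its knockdown libraries a and b, 52.7 M in the Daoy control, 56.9 M with Daoy shRNA 1 and 56.5 M with Daoy shRNA 2. SMARCB1, the gene whose loss defines most rhabdoid tumours, was at 0.0162, 0.0702 and 0.0206 CPM in CHLA-266 and at 49.0, 57.1 and 59.0 CPM in Daoy.

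HHIP-AS1 (ENSG00000248890, an antisense RNA on chromosome 4, 144642922 to 144661357, minus strand, GRCh38) was scarce in both lines and was lower in the Daoy knockdown libraries. Daoy had 30 HHIP-AS1 reads in the control, 6 with shRNA 1 and 13 with shRNA 2. The level with shRNA 1 was 18.5% of the control (ratio 0.185, 95% interval 0.0629 to 0.452, exact Poisson test p = 1.59e-05), and with shRNA 2 it was 40.4% (ratio 0.404, interval 0.193 to 0.797, exact p = 0.00553). These tests compare libraries, not conditions. CHLA-266 had 8 reads in the control and 5 and 6 in knockdown libraries a and b. Together these gave a ratio of 0.807 (interval 0.296 to 2.31, exact p = 0.641), so a reduction in CHLA-266 was not detectable at this depth. The Daoy control held 4.41 times the HHIP-AS1 level of the CHLA-266 control (interval 1.97 to 11.1, exact p = 5.23e-05).

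HHIP, the neighbouring gene for a Hedgehog-binding inhibitor (chromosome 4, 144646021 to 144745271, plus strand), overlaps HHIP-AS1. Of the 1557 exonic bases of HHIP-AS1, 178 also lie in exons of HHIP, and without strand the reads there cannot be told apart. HHIP was at 1.57 CPM in the CHLA-266 control and at 2.33 and 3.30 CPM on knockdown. In Daoy it was at 1.92 CPM in the control, 1.28 CPM with shRNA 1 and 6.24 CPM with shRNA 2. The change over both lines was 0.52 (SE 0.41), which did not pass the test (limma adjusted p = 1.00).

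**Figure D1:**
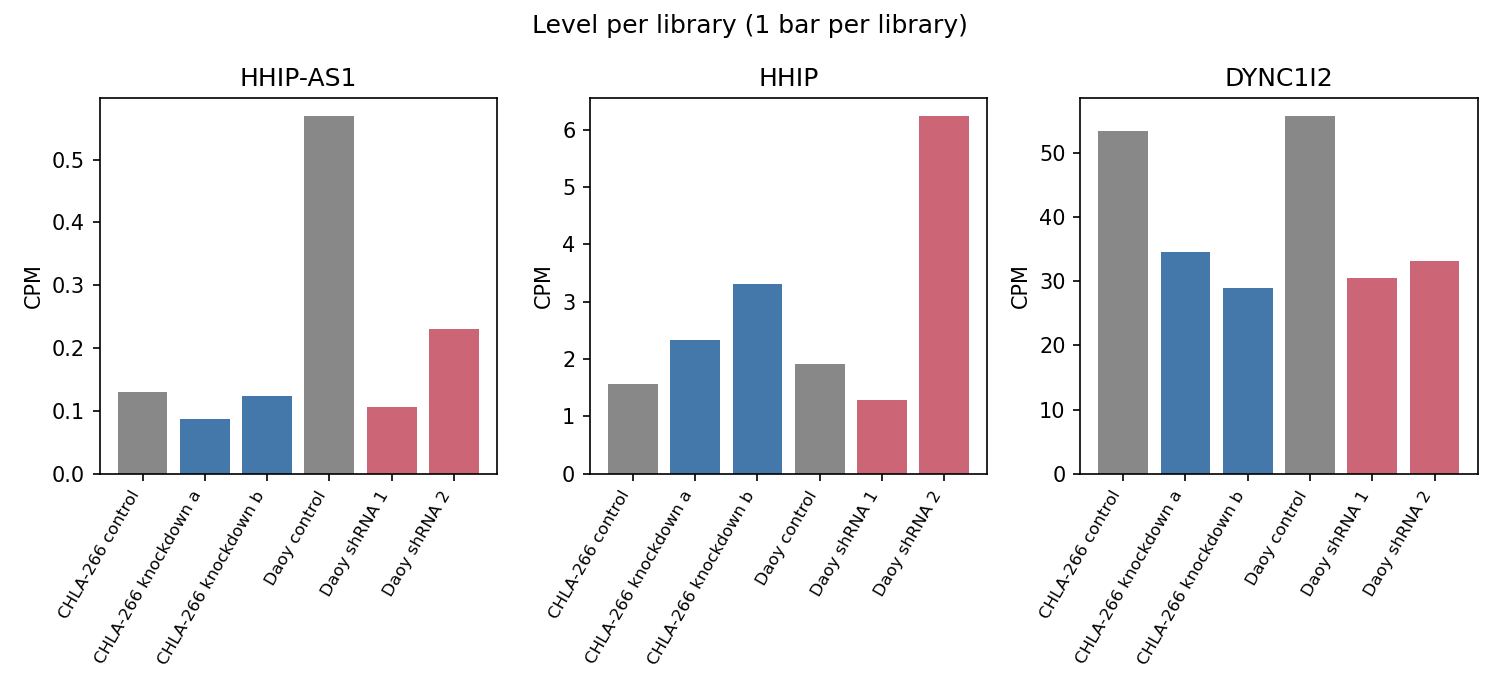
CPM (y axis, from 0) of HHIP-AS1, HHIP and DYNC1I2 in each of the 6 libraries (x axis; grey bars controls, coloured bars knockdown). HHIP-AS1 falls from 0.5698 CPM in the Daoy control to 0.105 and 0.230 CPM, while DYNC1I2 is at 53.5 and 55.8 CPM in the controls and between 29.02 and 34.6 CPM in the 4 knockdown libraries.

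The libraries differed far more by line than by treatment. Across the tested genes, which are not independent replicates, the correlation of log2 levels was 0.990 to 0.993 within CHLA-266 and 0.681 to 0.707 between the lines. Within Daoy it was 0.979 between the control and shRNA 1, 0.950 between the control and shRNA 2, and 0.956 between the shRNAs. The SD of the log2 changes against the control was 0.29 and 0.26 in CHLA-266 knockdown a and b, 0.38 with Daoy shRNA 1 and 0.61 with Daoy shRNA 2. The changes with Daoy shRNA 1 followed transcript GC content: over 13708 genes GC content and length accounted for 50.5% of their variance, against 5.95% and 3.22% in CHLA-266 and 3.02% with Daoy shRNA 2. The median change with Daoy shRNA 1 was −0.47 in the tenth of genes lowest in GC and 0.37 in the tenth highest in GC.

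**Figure D2:**
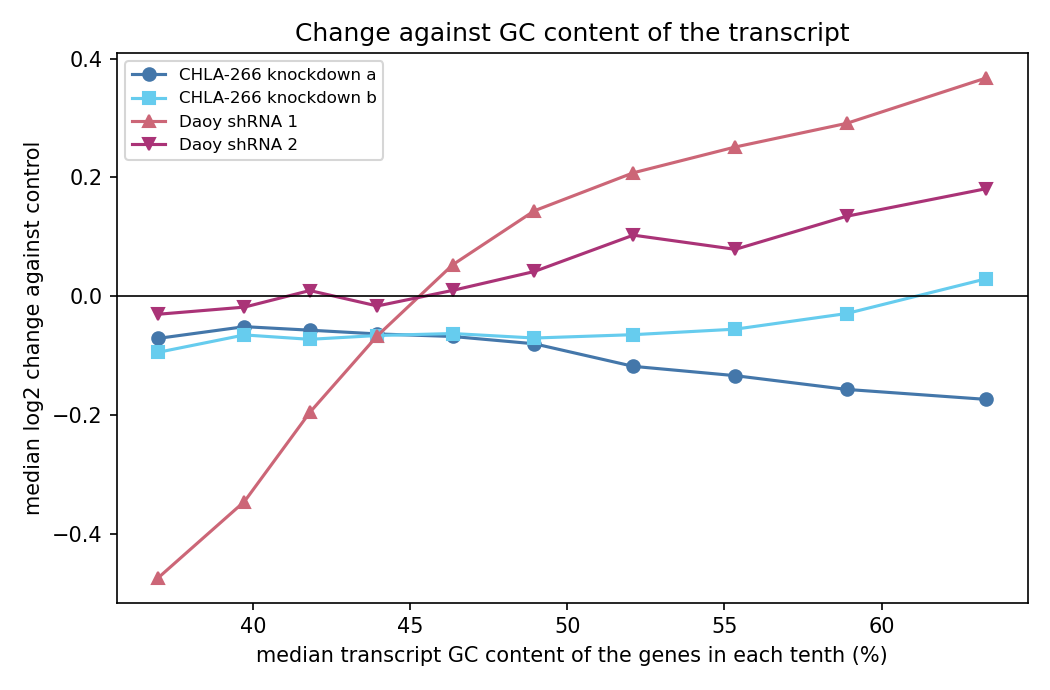
Median log2 change against the control of the line (y axis) in 10 equal groups of genes ordered by transcript GC content (x axis, median percent), 1 line per knockdown library. The line of Daoy shRNA 1 climbs from −0.47 to 0.37, while those of the other 3 libraries stay between −0.17 and 0.18.

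DYNC1I2, an intermediate chain of the motor cytoplasmic dynein and a gene this study is known to follow, was lower in all 4 knockdown libraries. It lies on chromosome 2, 171687409 to 171748420. Its level was 53.5 CPM in the CHLA-266 control against 34.6 and 29.02 CPM, and 55.8 CPM in the Daoy control against 30.5 and 33.1 CPM. The change over both lines was −0.77 (SE 0.16, 2 controls and 4 knockdown libraries). Its p of 0.00163 from limma before adjustment did not pass over all genes (limma adjusted p = 0.759). DYNC1I2 was among the dynein genes that passed when adjusted over the list alone. Because the study was known beforehand to follow DYNC1I2, passing in a short list that holds it is not independent support. The processed pseudogene DYNC1I2P1 was listed at 26.3, 17.9 and 16.0 CPM in CHLA-266 and 27.8, 17.1 and 18.8 CPM in Daoy, so part of these reads may be split between near-identical copies. The SHH targets GLI1 and PTCH1 did not pass either. GLI1 was at 12.2 CPM in the CHLA-266 control and 13.7 and 14.98 CPM on knockdown, and at 0.855 CPM in the Daoy control and 0.632 and 0.460 CPM on knockdown. PTCH1, the SHH receptor, was at 125 against 129 and 156 CPM in CHLA-266, and at 16.1 against 14.8 and 12.9 CPM in Daoy.

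Over both lines, 48 genes were at least 1.5-fold lower in all 4 knockdown-control pairs and 3 were at least 1.5-fold higher. The 4 pairs rest on 2 control libraries, 1 per line, and are not independent of each other. The 12 lower genes with the largest smallest change were NEK7, RAB21, TMEM47, RXFP1, ZMAT3, SPOPL, EML4, COMMD8, DENND1B, LIN7C, CRMP1 and ZNRF2. NEK7, a kinase of the NIMA family, was at 19.9 against 8.30 and 7.28 CPM in CHLA-266 and at 39.1 against 7.59 and 10.01 CPM in Daoy (log2 change −1.65, SE 0.23). RAB21, a small GTPase of endosomes, was at 71.2 against 21.4 and 22.8 CPM and at 30.8 against 10.8 and 13.5 CPM (−1.46, SE 0.18). ZMAT3, an RNA-binding protein gene and p53 target, was at 57.1 against 27.2 and 27.8 CPM and at 40.3 against 15.5 and 14.0 CPM (−1.21, SE 0.17). EML4, which encodes a microtubule-binding protein, was at 234 against 115 and 123 CPM and at 147 against 78.2 and 61.3 CPM. TMEM47 and RXFP1, the relaxin receptor gene, had changes of −1.61 (SE 0.21) and −1.50 (SE 0.21). In the remaining 6 genes the change lay between −1.12 and −0.98.

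The 3 higher genes were CH507-513H4.4, HSD17B10 and KIAA1549L. HSD17B10, a mitochondrial dehydrogenase gene, was at 17.5 against 36.4 and 36.8 CPM in CHLA-266 and at 19.0 against 35.3 and 35.0 CPM in Daoy (0.94, SE 0.15). KIAA1549L was at 3.81 against 7.93 and 10.2 CPM and at 10.01 against 17.9 and 23.1 CPM (1.00, SE 0.19). CH507-513H4.4, a clone-named gene without a match in the annotation, was at 39.3 against 80.03 and 74.98 CPM and at 103 against 1296 and 503 CPM. SCAND1, KIFC3, DYNLRB1, KLHL29, USP40, TMED4, NCS1, HIST3H2A and PPP2R3B completed the 12 higher genes, with changes of 0.50 to 1.01. KIFC3, a kinesin of the minus-end-directed kind, was at 4.07 against 7.48 and 9.47 CPM and at 6.44 against 9.82 and 23.5 CPM. DYNLRB1, a dynein light chain gene, was at 12.03 against 22.4 and 24.1 CPM and at 15.4 against 24.3 and 22.4 CPM.

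None of these changes passed the test. For knockdown against control over both lines, limma called 0 of 15214 genes (smallest adjusted p = 0.489), with 431 lower and 78 higher genes at an unadjusted p under 0.05 where 761 are expected by chance. With trends on GC content and transcript length removed, which could be done for 47 of the 48 lower genes, 31 genes were lower and 2 higher at 1.5-fold, while the median change of the 47 was −0.96 (SD 0.25) before and −0.85 (SD 0.27) after. Without Daoy shRNA 1, 101 were lower and 8 higher in the other 3 pairs.

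**Figure D3:**
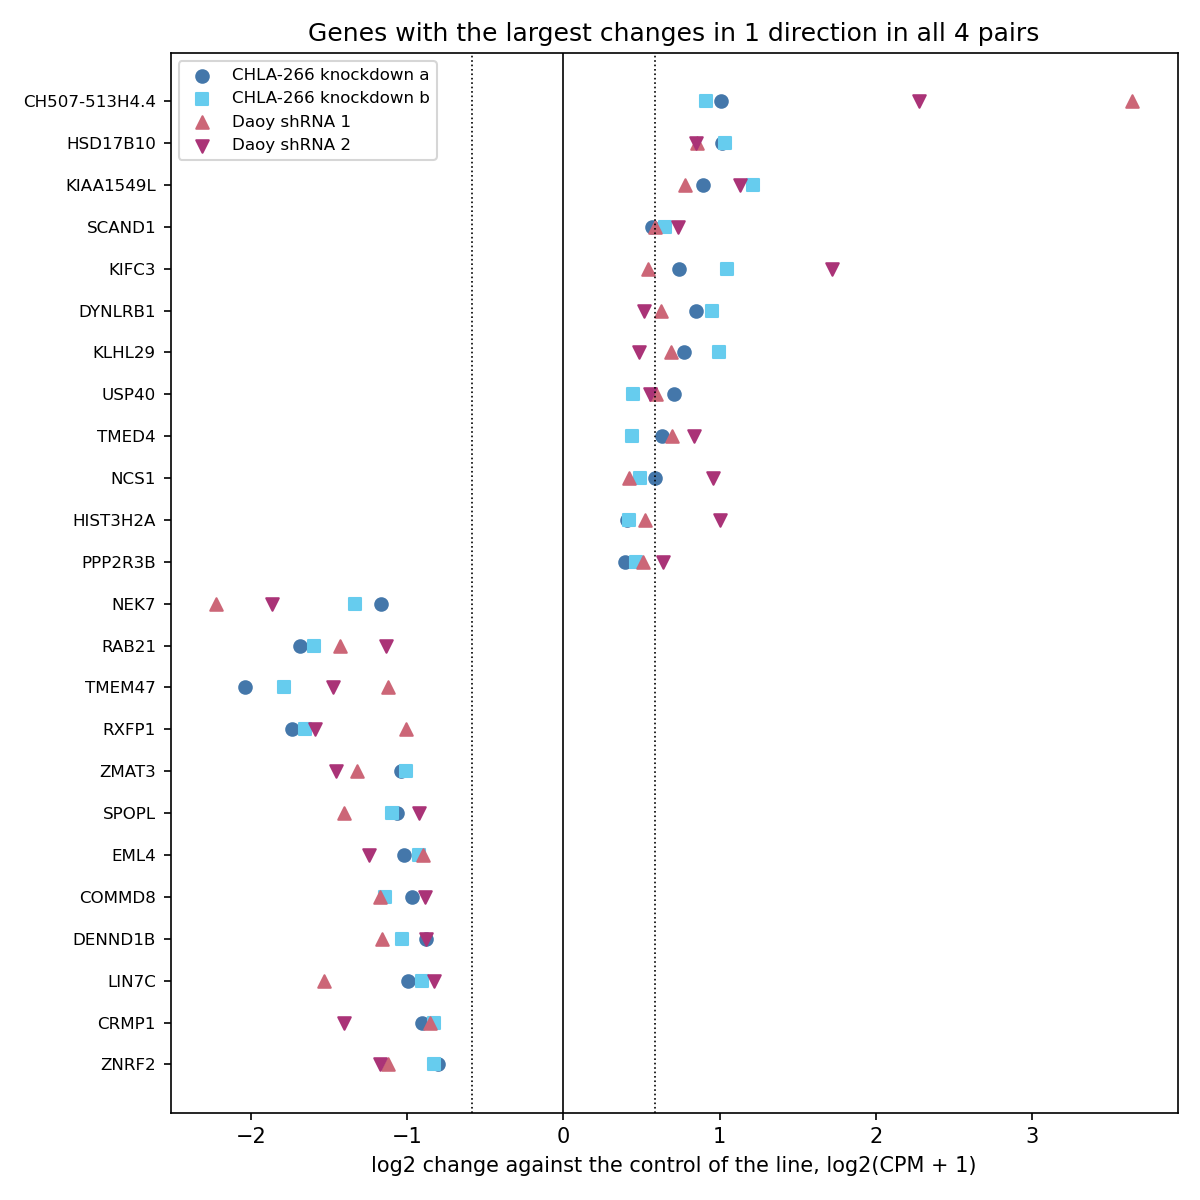
Log2 change on the log2(CPM + 1) scale (x axis) of the 12 higher and 12 lower genes (y axis) in each knockdown library against the control of its line, 1 point per library, with dotted lines at 1.5-fold. The points of NEK7 and RAB21 lie below −1.1 in all 4 pairs and those of HSD17B10 lie above 0.8.

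Of the lists tested over both lines, DNA replication genes and p53 target genes passed with the preset correlation. DNA replication genes were higher relative to other genes (limma camera adjusted p = 0.000778, median change 0.19, 23 of 26 members above 0), a call lost with an adjusted p = 0.934 with an estimated correlation. Members with the largest change were RRM2 (0.51, SE 0.46), E2F1 (0.44, SE 0.31), UHRF1 (0.36, SE 0.26) and MCM2 (0.35, SE 0.18). The list medians per library were −0.06 and −0.16 in CHLA-266 against 0.22 and 0.69 in Daoy. Without Daoy shRNA 2, the library farthest from the others, the call was lost (limma camera adjusted p = 0.459). It was also lost without the Daoy control, where the comparison rests on CHLA-266 alone. The p53 targets were lower (limma camera adjusted p = 0.0223, median −0.18, 15 of 21 members below 0), again with an adjusted p = 0.934 with an estimated correlation. ZMAT3, FAS (−0.93, SE 0.39), PHLDA3 (−0.90, SE 0.60) and TP53INP1 (−0.62, SE 0.31) were the members with the largest change. Without the CHLA-266 control, where the comparison rests on Daoy alone, this call was lost. Without CHLA-266 knockdown a its limma camera adjusted p was 0.0503. No member of the 18 lists passed over all genes. Adjusted over the list alone, 1 p53 target was called lower, and in 16 of the 18 lists no member was called.

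The cytoplasmic dynein 1 subunits did not shift as a list (limma camera adjusted p = 0.819, median 0.05, 6 of 10 above 0). Adjusted over the list alone, 1 subunit was called higher and 2 lower. The lower ones were DYNC1I2 and DYNLT3 (−0.56, SE 0.17) and the higher one was DYNLRB1 (0.73, SE 0.17), while DYNLL2, with a change of 0.46 (SE 0.16), did not pass. Dynactin and dynein regulators had a median of −0.03 (limma camera adjusted p = 0.819). In this list DCTN4 (−0.43, SE 0.16) and PAFAH1B1 (−0.40, SE 0.16) showed the largest changes. Hedgehog pathway components (adjusted p = 0.819 from limma camera, median −0.10) and Hedgehog target genes (adjusted p = 0.388 from limma camera, median 0.12) did not pass. GAS1, an SHH co-receptor gene, was at 41.6 against 39.1 and 30.8 CPM in CHLA-266 and at 60.9 against 51.6 and 4.21 CPM in Daoy, and BOC, another co-receptor gene, had a change of −0.75 (SE 0.52). Mitosis genes (median 0.04), apoptosis regulators (−0.08), interferon response genes (−0.29), NF-kB and cytokine genes (−0.08), stress response genes (0.07) and cholesterol synthesis genes (−0.08) did not pass. Neither did hypoxia and glycolysis genes (median −0.01), oxidative phosphorylation genes (0.05), ribosomal proteins (0.02), extracellular matrix genes (−0.05), neuronal differentiation genes (−0.23) or neural stem and progenitor genes (−0.31). The adjusted p from limma camera of these 12 lists lay between 0.161 and 0.957. The test pointed upward for the NF-kB, hypoxia and extracellular matrix lists although their medians lay below 0, since it compares a list with all other genes by a moderated statistic. The mean of the dynein subunits was −0.003 although their median lay above 0.

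Markers of other cell types were few. Of 10 blood and immune markers only CD68 was tested, at 0.0907, 0.0552 and 0.0665 CPM in CHLA-266 and 1.96, 1.77 and 2.80 CPM in Daoy. TEK, an endothelial marker, was at 2.68, 5.79 and 3.40 CPM in CHLA-266 and 7.12, 4.11 and 5.43 CPM in Daoy. Of the epithelial markers, KRT8 was at 170 against 50.7 and 55.6 CPM in CHLA-266 and 47.0 against 30.3 and 28.7 CPM in Daoy. CDH1 was at 26.7 against 14.7 and 14.9 CPM and EPCAM at 357 against 336 and 252 CPM in CHLA-266. KRT18 was at 189 against 205 and 281 CPM in Daoy. The median change of the 4 tested epithelial markers was −0.45 and −0.65 in CHLA-266 knockdown a and b. It was −0.32 with Daoy shRNA 1 and −0.48 with Daoy shRNA 2.

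**Figure D4:**
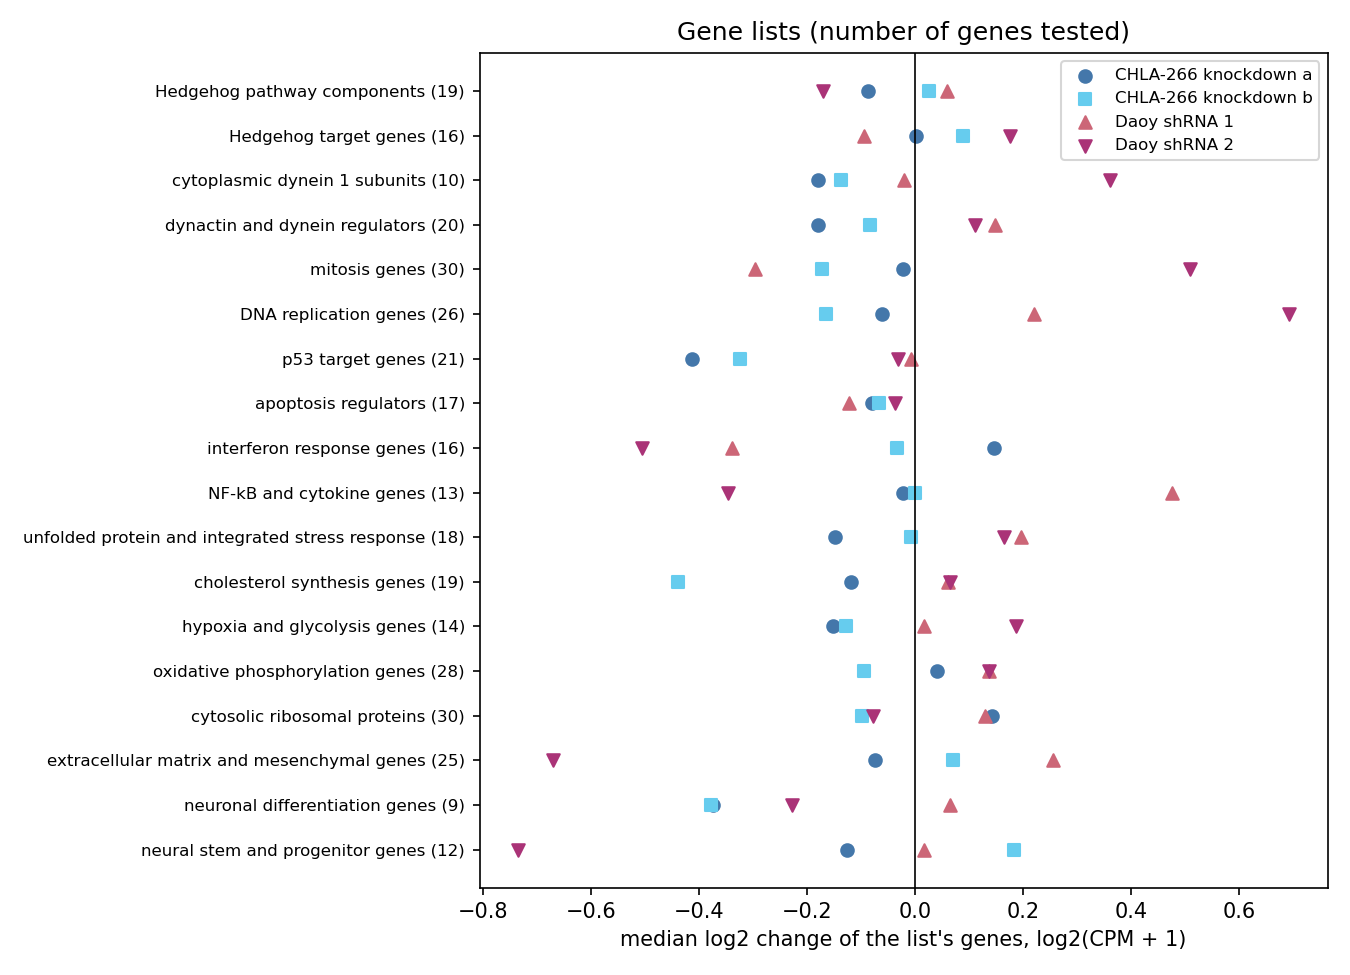
Median log2 change of the genes of each of the 18 lists (y axis, number of tested genes in brackets; x axis on the log2(CPM + 1) scale), 1 point per knockdown library against the control of its line. The DNA replication genes lie at 0.22 and 0.69 in Daoy and below 0 in CHLA-266, and the p53 targets lie at −0.41 and −0.32 in CHLA-266 and near 0 in Daoy.

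Within CHLA-266, the largest changes among genes with a mean of at least 10 CPM were those of PDGFRB, ADGRG6, LUM, DCN and SPARC upward and of KRT8, SLC1A1, RAB21, KRT8P3 and STC2 downward. PDGFRB, a growth factor receptor gene, was at 2.62 CPM in the control and 16.2 and 15.3 CPM on knockdown (log2 change 2.21, SE 0.66). ADGRG6, an adhesion receptor gene, was at 16.0 against 77.8 and 61.8 CPM. The matrix proteoglycan genes LUM and DCN were at 20.9 against 104 and 59.9 CPM and at 21.6 against 114 and 56.7 CPM, and SPARC was at 13.2 against 33.0 and 47.7 CPM. KRT8 had a change of −1.66 (SE 0.21), and its pseudogene KRT8P3, with which it may share reads, −1.64 (SE 0.24). RAB21 (−1.64, SE 0.23), the glutamate transporter gene SLC1A1 (28.7 against 10.8 and 6.56 CPM) and STC2 (8.31 against 2.67 and 2.23 CPM) were the others. As a list, extracellular matrix and mesenchymal genes did not pass in CHLA-266 (limma camera adjusted p = 0.0635, pointing upward although the median was −0.07 and 16 of 25 members lay below 0). limma called 0 genes (smallest adjusted p = 1.00), with 239 lower and 74 higher at an unadjusted p under 0.05.

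The p53 targets were lower than other genes in CHLA-266 (limma camera adjusted p = 0.000722, median −0.37, 18 of 21 below 0), and so were cholesterol synthesis genes (limma camera adjusted p = 0.0252, median −0.25, 18 of 19 below 0). Neither call held in limma camera, with adjusted p = 0.828 and 0.929 with an estimated correlation. ZMAT3 (−1.03, SE 0.21), FAS (25.8 against 16.0 and 15.5 CPM) and BAX (41.8 against 29.5 and 29.3 CPM) were among the former, SQLE (51.7 against 38.8 and 34.4 CPM) and HMGCS1 (99.8 against 78.6 and 64.9 CPM) among the latter. Interferon response genes passed as higher (limma camera adjusted p = 0.0271, but adjusted p = 0.929 with an estimated correlation) although their median was only 0.04 and 8 of 16 lay below 0. IFI44L (5.74 against 16.6 and 14.5 CPM) had the largest change in that list, and IFIH1 (43.1 against 31.3 and 25.8 CPM) the next, downward. The cholesterol call was lost without CHLA-266 knockdown b (limma camera adjusted p = 0.936) and without either Daoy knockdown library (0.193 and 0.176), which enter through the shared spread. The interferon call was lost without CHLA-266 knockdown a (limma camera adjusted p = 0.547) and without either Daoy knockdown library (0.204 and 0.176). Adjusted over the list alone, 2 neural stem and progenitor genes were called higher. SOX11 was at 1.58 against 5.02 and 4.48 CPM and PAX6 at 4.32 against 10.2 and 9.60 CPM.

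Within Daoy, the genes with the largest changes moved mainly with shRNA 2, apart from CH507-513H4.4 and SESN3. CH507-513H4.4 was at 1296 CPM with shRNA 1 and 503 CPM with shRNA 2. COL3A1, a collagen gene, was at 604 CPM in the control, 312 CPM with shRNA 1 and 3.40 CPM with shRNA 2. IGFBP5 was at 835, 551 and 18.3 CPM in the same order, CHRNA9 at 137, 75.6 and 4.76 CPM, and PDE4B at 94.4, 55.6 and 2.76 CPM. SESN3, a sestrin gene, was lower with both shRNAs, at 167 CPM against 34.7 and 10.3 CPM (log2 change −3.07, SE 0.68). Among higher genes, CPA4 was at 8.95, 16.9 and 92.0 CPM, GPAT3 was at 4.80, 8.85 and 47.1 CPM and ALDH1A3 at 7.69, 7.66 and 94.4 CPM. limma called 0 genes in Daoy (smallest adjusted p = 0.690), with 512 lower and 436 higher at an unadjusted p under 0.05. Without Daoy shRNA 1 limma called 360 genes, in a fit in which the lone Daoy libraries are assumed to vary like those of CHLA-266.

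DNA replication genes were higher relative to other genes in Daoy (limma camera adjusted p = 4.56e-05, median 0.45, 25 of 26 above 0), and interferon response genes lower (limma camera adjusted p = 0.00118, median −0.48, 13 of 16 below 0). Both calls were lost in limma camera, with an adjusted p = 0.953 with an estimated correlation for each. RRM2 was at 78.7 CPM in the control, 112 CPM with shRNA 1 and 321 CPM with shRNA 2, E2F1 at 9.74, 12.9 and 26.1 CPM and UHRF1 at 25.1, 34.3 and 54.7 CPM. IFITM1 was at 6.84, 2.87 and 0.200 CPM, IFIT1 at 8.74, 3.55 and 3.93 CPM, and IFIT2 at 13.8, 5.20 and 8.42 CPM. Without Daoy shRNA 2 both calls were lost, with adjusted p values from limma camera of 0.274 for DNA replication and 0.0531 for interferon response. Adjusted over the list alone, 1 p53 target was called lower in Daoy.

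The Daoy shRNAs were also set side by side, with 1 library each and no test. Genes at least 2-fold lower than the control numbered 109 with shRNA 1 and 708 with shRNA 2, and those at least 2-fold higher numbered 49 and 487. With shRNA 1 the largest changes were CH507-513H4.4, RAVER1 (1.30), PLEC (1.26), ZYX (1.26) and MSC (1.25) upward, and SESN3 (−2.24), NEK7 (−2.22), CSRNP3 (−1.73), SMAD5 (−1.63) and GPAM (−1.61) downward, in the library whose changes followed GC content. With shRNA 2, ALDH1A3, CPA4, GPAT3 and THBS1 (67.8 CPM in the control, 511 CPM with shRNA 2) led upward, and COL3A1, IGFBP5, PDE4B, CHRNA9 and VCAM1 (565 CPM in the control, 23.7 CPM with shRNA 2) downward. Directly between the shRNAs, SYNC (2.07 against 30.4 CPM), SLC7A11 (3.16 against 36.6 CPM), STC2 (11.3 against 80.9 CPM), ALDH1A3 and THBS1 were higher with shRNA 2, and MXRA5 (108 against 5.62 CPM) was among the lower genes, beside COL3A1, IGFBP5, VCAM1 and PDE4B. Across genes the changes of the shRNAs of a line correlated at r = 0.402 in Daoy and 0.599 in CHLA-266, where simulated unchanged libraries that share a control gave 0.4994 and 0.4997. The covariance was 0.0942 against a simulated 0.0619 in Daoy and 0.0446 against 0.0122 in CHLA-266. The simulated spread was read from a smooth curve that follows typical genes. Genes that vary widely therefore raise the measured covariance but not the simulated one. The gap between measured and simulated covariance thus cannot be read as an effect of the shRNAs. The simulation also let the shared control vary like the shRNA libraries, and a control that varied more would widen the gap.

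The responses of the lines were not correlated across genes. Between the mean changes in CHLA-266 and in Daoy, Pearson's r was 0.00 and Spearman's rho −0.03 over 15214 genes, and 45.4% of genes had the same sign. Genes at least 2-fold lower in both lines numbered 10, where independent lists of 77 and 280 genes would share 1.42. At least 2-fold higher in both were 0 genes, where lists of 30 and 121 would share 0.239. The test of the difference in response called 0 genes (limma, smallest adjusted p = 0.928), with 292 higher and 180 lower at an unadjusted p under 0.05. Without Daoy shRNA 1, limma called 66. STC2, GPAT3, KIF1A and PLAU were at the upper end of Daoy minus CHLA-266, and COL3A1, ADGRG6, PDGFRB, SESN3 and STON1 at the lower end. KIF1A, a neuronal kinesin gene, was at 325 against 162 and 179 CPM in CHLA-266 and at 15.7 against 22.8 and 57.5 CPM in Daoy. ADGRG6 was at 18.8 against 7.99 and 2.76 CPM and PDGFRB at 25.9 against 16.9 and 4.70 CPM in Daoy, opposite to their direction in CHLA-266. As lists, interferon response genes were lower in the Daoy response (limma camera adjusted p = 3.42e-05, median −0.65) and DNA replication genes higher (limma camera adjusted p = 0.000645, median 0.52). With an estimated correlation the adjusted p from limma camera was 0.862 for each. The DNA replication difference was lost without Daoy shRNA 2 (limma camera adjusted p = 0.236). Adjusted over the list alone, 2 neural stem and progenitor genes, PAX6 (−1.48, SE 0.31) and SOX11 (−1.25, SE 0.30), were called lower in the Daoy response.

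Daoy and CHLA-266 themselves differed in 8550 of 15214 genes at an adjusted p under 0.05 from limma, 5098 higher and 3452 lower in Daoy. TGFBI was at 1550 to 2920 CPM in Daoy and at most 0.0485 CPM in CHLA-266, and FN1, the fibronectin gene, at 3911 to 10555 CPM against 3.18 to 5.72 CPM. COL6A3, TNC, CCL2, MSN, TAGLN2 and COL4A2 were also higher, with log2 differences of 7.83 to 9.93. FREM2, TTN, PI15, DSEL, FAM9C, PCDH17 and LIX1 were higher in CHLA-266, with log2 differences of −10.00 to −8.15. FREM2, a basement membrane protein gene, was at 1662 to 1871 CPM in CHLA-266 and 0.336 to 1.65 CPM in Daoy. The adjusted p from limma of these genes was at most 3.19e-06. The median difference over all genes was 0.14, and with the listed genes scaled to a common sum it was 0.00 and the calls were 4371 higher and 4215 lower.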

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

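The results given here were picked by a fixed rule, a difference between the lines in the knockdown response, and only the share of such genes among all tested genes was chosen after the result was seen. No group held the 4 libraries needed to test for a single library that stands apart.

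For 2 gene lists the test of the difference in response passed. DNA replication genes were higher in the Daoy response than in that of CHLA-266 (limma camera adjusted p = 0.000645, with an adjusted p = 0.862 with an estimated correlation), and all 26 members lay above 0. Interferon response genes were lower in the Daoy response (limma camera adjusted p = 3.42e-05, with an adjusted p = 0.862 with an estimated correlation), and 14 of 16 members lay below 0. In this fit the estimated correlation among the DNA replication genes was 0.837, so these genes moved almost as 1 value. Among the interferon response genes it was 0.0638, so the loss of their call cannot be laid to high correlation.

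Both knockdown libraries of one line lay on one side of their control and both of the other line on the opposite side in 27 of the 109 genes that the naming rule takes or the text names (24.8%), against 25.4% of all 15214 tested genes. In none of the 27 did the limma test of the difference pass over all genes (adjusted p = 0.928 to 0.938). All differences are Daoy minus CHLA-266 on the log2 scale. The Hedgehog targets GLI1 and PTCH1 differed by −0.48 (SE 0.32) and −0.39 (SE 0.33). Of the genes with the largest changes within a line or between the responses, COL3A1 differed by −5.03 (SE 3.30), ADGRG6 by −3.81 (SE 0.75), PDGFRB by −3.62 (SE 0.93), SESN3 by −3.34 (SE 0.96), STON1, an endocytosis gene, by −2.96 (SE 1.19), LUM by −2.27 (SE 0.55) and SPARC by −2.06 (SE 0.56). In the other direction STC2 differed by 2.89 (SE 1.49), GPAT3 by 2.23 (SE 1.26), KIF1A by 2.09 (SE 0.75) and the urokinase gene PLAU by 2.09 (SE 1.03). Among genes named for their difference between the lines themselves, FREM2 differed by −1.07 (SE 0.29), DSEL by −0.87 (SE 0.30), PCDH17 by −0.55 (SE 0.30), MSN by 0.38 (SE 0.30) and TAGLN2 by 0.30 (SE 0.31). Among list members, PAX6 differed by −1.48 (SE 0.31) and SOX11 by −1.25 (SE 0.30), the pair that passed when adjusted over the list alone, MAP2 by −2.19 (SE 0.87), TEK by −1.07 (SE 0.48), KRT18 by 0.36 (SE 0.38), UHRF1 by 0.81 (SE 0.45), BAX by 1.01 (SE 0.28), RRM2 by 1.49 (SE 0.86) and TUBB3 by 1.83 (SE 0.95).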

How the results depend on the processing

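The replicate block under both numberings of the CHLA-266 columns, scaling to a common sum, limiting to protein-coding genes, removing a GC and length trend and leaving single knockdown libraries out of the count of genes changed the same way were chosen after the data were seen. The shRNA number of the CHLA-266 knockdown columns was not settled, so the planned replicate block was fitted with a and with b taken as shRNA 1. Either way limma called 0 genes over both lines (smallest adjusted p = 0.615 and 0.282), in each line and for the difference. With the replicate block and a as shRNA 1, 5 lists were called in CHLA-266, and with b as shRNA 1 the interferon call there was lost (limma camera adjusted p = 0.0529), while no other list call made without the block was lost. In the fit with line and construct limma called 0 genes for shRNA 1, for shRNA 2 and for shRNA 2 against shRNA 1, with 287, 741 and 344 genes at an unadjusted p under 0.05 with a as shRNA 1 and 461, 819 and 718 with b. The other alternatives planned for these tests were not run. For knockdown over both lines limma called 0 genes in all 19 alternatives. The 29 genes named for that comparison had 516 values under alternatives, of which 503 kept their direction and 0 passed the threshold (lowest adjusted p = 0.0603). The cause of the shifts below was not tested unless given.

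With an estimated correlation 0 lists passed in each of the 4 comparisons. That setting tests on 2 or 3 degrees of freedom, so hardly any list could pass and the count decides nothing. The p53 targets in CHLA-266 had an estimated correlation of −0.0075, below the preset one. Their unadjusted p from limma camera still went from 4.01e-05 to 0.0460. The count of lists called in CHLA-266, 3 as reported, was 5 with a pseudocount of 0.25 CPM, with a mean of at least 5 CPM, with trimmed-mean scaling, with listed genes scaled to a common sum and with protein-coding genes. Without the GC and length trend it was 4 in Daoy and 6 for the difference between lines, where 2 were called for each. Genes lower in all 4 pairs numbered 5 at 2-fold, 74 with a pseudocount of 0.25 CPM, 19 with 5 CPM and 31 without the GC and length trend. Higher ones numbered 0 at 2-fold and 6 with 0.25 CPM. Of the 48 lower genes, 39 were shared with trimmed-mean scaling, 38 with median centring and 43 with the common sum. The change of GLI1 over both lines turned to 0.0443 with a pseudocount of 5 CPM, 0.0034 with trimmed-mean scaling and 0.0030 with median centring. That of PTCH1 turned to 0.0090, 0.00098 and 0.0192 under these settings, to 0.0317 with the common sum and to 0.0079 without the GC and length trend. Median centring moved the median change of CHLA-266 knockdown a from −0.09 to 0.04. From the 2 controls alone limma called 3959 genes between the lines, with fewer libraries in the contrast.

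Leaving out 1 library at a time gave −0.26 to 0.21 for GLI1 and −0.21 to 0.19 for PTCH1, since without a control only the other line is left. It gave 0 to 360 called genes in Daoy and 0 to 66 for the difference between lines, the upper ends without Daoy shRNA 1. Called lists ranged from 2 to 6 over both lines, 1 to 5 in CHLA-266, 1 to 5 in Daoy and 2 to 6 for the difference. Genes changed the same way in the remaining 3 pairs numbered 61 to 101 lower and 5 to 13 higher, where fewer pairs must pass. The correlation of the responses of the lines ranged from −0.11 without CHLA-266 knockdown b to 0.13 without knockdown a. In CHLA-266 the interferon call was also lost with a pseudocount of 5 CPM, without a filter and with median centring (limma camera adjusted p = 0.0641, 0.390 and 0.0531), and the cholesterol call without a filter (0.0598). HHIP-AS1, at 5 to 30 reads per library, is limited by depth.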

Other observations

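The tests of control choices, pseudogenes, library depth and other splits of the libraries, and the limits for the GC and untranslated region trends, were chosen after the result was seen.

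In Daoy several lists went opposite ways with the shRNAs, as values without a test. The median of the 30 mitosis genes was −0.30 with shRNA 1 and 0.51 with shRNA 2, and that of the 25 extracellular matrix and mesenchymal genes was 0.26 and −0.67. NF-kB and cytokine genes stood at 0.48 and −0.35. Neural stem and progenitor genes were at 0.02 with shRNA 1 and −0.74 with shRNA 2. These list medians were not corrected for the GC trend of the shRNA 1 library. GC content and length accounted for 50.5% of the variance of the changes in that library. Its median change was −0.47 in the group of genes lowest in GC and 0.37 in the group highest in GC. The opposite directions may therefore come in part from that trend. MAP2, a neuronal microtubule gene, had a mean change in Daoy of −1.93 (SE 0.62), and TUBB3, a neuronal tubulin gene, of 1.33 (SE 0.67).

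Genes lower in all 4 pairs (48) outnumbered the higher ones (3). The pairs of a line share its control, so a level particular to that control enters both and cannot be told apart from knockdown. Reads shared with pseudogenes stay open: 93.8% of the lower genes were protein-coding, but genes that share reads with their pseudogenes are protein-coding too, so this share decides nothing. With transcript GC content and length removed, 31 genes were lower (25 of them among the 47 before), and with 3′ untranslated region length and GC content removed 20 were (19 of the 45 before), but the median change of these 47 and 45 genes went from −0.96 to −0.85 in each case (SD 0.25 before, 0.27 and 0.26 after). In Daoy shRNA 1, the library with the GC trend, the median of these genes went from −0.85 (SD 0.35) to −0.65 (SD 0.34) and 18 of 47 came to lie under 1.5-fold with the first correction, and from −0.87 (SD 0.35) to −0.62 (SD 0.34) and 21 of 45 with the second, against 11 and 14 with Daoy shRNA 2 and 1 in each CHLA-266 library, so either trend may account for part of the change in Daoy, and an effect of HHIP-AS1 loss, for which no biological test was run, stays open too. Only 1 of 9 choices of a library per line as the control gave 51 genes, with 37 the highest of the others, and 9 choices are too few for a share under 0.05.

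Daoy shRNA 2 lay far from the other Daoy libraries. Depth is argued against: its 56.5 M reads compare with 52.7 and 56.9 M, and over genes of at least 50 CPM the SD of its changes was 1.48 times that of shRNA 1. A GC and length trend is argued against too: it accounted for 3.02% of the variance of the shRNA 2 changes, and with it removed their SD was 0.61 (0.62 before), 1.58 times the uncorrected 0.39 of shRNA 1. An effect of that shRNA other than on HHIP-AS1, or a difference between cultures, may remain, and with 1 library these cannot be separated.

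The study is known to follow DYNC1I2, and a hypothesis was that loss of HHIP-AS1 could free the microRNA miR-425-5p to act on genes with its seed site. The 3′ untranslated region of DYNC1I2 holds 1 such site. Over 12174 genes, those with a site (1507) differed from the rest by −0.05 in their change over both lines, and by −0.002 after correction for the length and GC content of the region. Of 15962 words of 7 bases, 40.6% gave a lower difference, so these data gave no sign of a general shift of such genes. The share was 7.20% in CHLA-266 and 73.3% in Daoy. HHIP-AS1 had only 5 to 30 reads per library, and its reduction in CHLA-266 was not detectable, so a shift may be too small to show. Whether HHIP-AS1 holds a site was not examined. A lack of a general shift does not bear on an effect on DYNC1I2 alone.

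Between the lines, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 8550 genes and the highest of the others gave 0, and 10 splits are too few for a share under 0.05. Every other split mixes the lines and puts their difference into the spread, so few or no calls were bound to follow. The splits therefore cannot decide about chance.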
